A study of Prunus persica with 20 samples.

How the data were processed

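Messenger RNA was sequenced from young fruit of 4 peach (*Prunus persica*) accessions, and a gene-level count table with 19 libraries was analysed. Per the labels' protocols, total RNA was taken at fruit set with the RNeasy Plant Mini Kit and libraries were made with the TruSeq Stranded mRNA kit. The deposited table holds estimated counts per gene, all of them whole numbers (0 values were not whole), without normalization. RSEM 1.2.31, Bowtie2 2.5.1, DESeq2 and R 4.1.1 are named in the submitters' processing notes with no role attached to any of them. The genome build, the strand setting and the read filters are not given in the sources used here. How reads shared by near-identical genes were divided is not recorded either, so a level of a gene with close copies is uncertain, and overlapping or antisense genes could not be checked.

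The groups follow the sample titles: MN (the Maravilha nectarine mutant, stated Gg), Sunraycer (a nectarine, stated gg), TN11 (a peach, stated GG) and TN7 (a peach, stated Gg). There were 5 libraries of MN, 5 of Sunraycer, 5 of TN11 and 4 of TN7. Replicate 4 of TN7 was not analysed here. Every column of the table matched a sample title (0 columns were left unmatched). Nothing says whether the replicates were separate trees or separate fruits, so p-values measure the spread between these samples, which may be technical. GG, gg and each combination of genotype and surface were represented by a single accession. MN and Sunraycer are the only nectarines, TN7 and TN11 the only peaches, and MN and TN7 the only accessions stated Gg. With so few accessions, a difference of genotype or surface cannot be told apart from other differences between them. No sequencing batch or date is given in the labels. The 3 pairs of MN and TN7 libraries with the same replicate number deviated together (correlations 0.419 to 0.486 across genes), a possible hint of pairing from the data alone. The main direction of spread between libraries was similar within MN and within TN7 (correlation 0.678 across genes), so it could give such values without pairing. No other pair of accessions had all of its same-numbered libraries correlated above 0.1, and the fit was made without a block. No pair of libraries within an accession differed by sampling noise alone: the smallest chi-square per degree of freedom between libraries, over genes with at least 10 counts, was 7.13.

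The table has 26811 genes, of which 2286 had no count in any library. The filterByExpr function of edgeR kept 19360 genes and left 7451 untested. Counts were scaled with TMM factors and fitted with edgeR's quasi-likelihood model (glmQLFit, glmQLFTest), with one mean per accession and a dispersion shared over the 19 libraries. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 and its difference was at least 2-fold (1 on the log2 scale). The standard error of a log2 fold change is its size divided by the square root of the F statistic. Fits were made for the 6 pairs of accessions and for the difference between MN minus TN7 and Sunraycer minus TN11, called the interaction. A gene was counted as shared by nectarines when it was called in the same direction in all 4 comparisons of a nectarine with a peach. The same count was made for the other ways to pair the accessions, and a gene was counted as an accession's own when it was called in the same direction against each of the others. CPM values are counts scaled to a common library size (TMM), given as mean ± SD. Where a group had no count of a gene, the fold is a lower bound against 3 counts over that group; with 1 to 3 counts it is the ratio with an exact Poisson interval at 95%, which covers counting error only. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and SciPy 1.17.1.

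Library totals ran from 14890206 to 24474843 counts. Counts were simulated from the real means and library sizes, with 200 changed genes among 19296 tested. The changed genes were drawn only from those with a mean of at least 1 CPM, so recovery of genes below that level was not measured. On these counts the MN minus TN7 comparison recovered 92% of 4-fold and 33% of 2-fold changes and called 8 unchanged genes. The Sunraycer minus TN11 comparison recovered 94% of 4-fold and 33% of 2-fold changes and called 5 unchanged genes. The shared set held 92% of the 4-fold changes and 0 unchanged genes. A change of 2-fold was missed more often than found in these simulated comparisons, in part because a call requires an estimate of at least 2-fold, whatever the depth. Simulated genes varied independently of each other, without a direction of spread shared by many genes, so these rates need not hold for the real data.

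The comparisons, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for 4 of the comparisons, for the shared set and for MN's own set, the 5 called genes with the largest positive and the 5 with the largest negative log2 fold change, among genes with a mean of at least 5 CPM in the higher group and no overlap between libraries of the groups compared. The rule also asked for a product description, which could not be applied. The files do not pair the gene identifiers with names, and 0 of the identifiers matched the RefSeq gene table supplied. For that reason the first 2 in each direction are printed, by identifier. The exception is Prupe.5G196100.v2.1, chosen in advance from published work on peach as the MYB gene PpMYB25 at the G locus. Gene lists defined by product descriptions (regulators of trichomes, cuticle and wax, flavonoids, cell wall, hormones and others), with markers of other tissues, were planned for camera and fry and were not run, for the same reason. GC content and gene length were not used here. The chromosome of a gene and its order along it were read from the identifier, and no coordinates are given.

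The alternatives were DESeq2 size factors in edgeR, no low count filter, a filter of at least 1 CPM in at least 5 libraries, DESeq2, limma-voom, the replicate number of the labels as a block, adjusted p alone, glmTreat, fits on the groups compared alone, and leaving out each library in turn. After the data were seen, further fits were added: without Sunraycer 1 and TN7 5, the libraries farthest from the rest of their accession, and with an axis score as a covariate. The axis score places each library on the main direction of spread between libraries within the other accessions, computed from log2 CPM (prior count 2) without using the spread of the library's own accession. On simulated counts with no such direction, the gene slopes of different accessions correlated by at most 0.0426 in size, and with a planted one by at least 0.664. The planted direction had a chosen strength and the same dispersion for all genes, while the counts without it used gene-wise dispersions. The value of 0.664 is therefore no yardstick for the real data. Single values were compared with exact two-sided permutation tests.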

Results

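Fruit at the fruit set stage was profiled by RNA sequencing in 4 accessions that differ in fruit hair and in the stated genotype at G, the locus that separates fuzzy peaches from smooth nectarines. TN11 is a peach stated GG and TN7 a peach stated Gg. Sunraycer is a nectarine stated gg. MN, the Maravilha nectarine mutant, arose from a peach and is smooth although it is stated Gg. The stated purpose was to learn how trichome development is regulated, in MN above all. The libraries numbered 5 for TN11, 4 for TN7, 5 for MN and 5 for Sunraycer. Total counts per library lay between 14890206 (Sunraycer 3) and 24474843 (Sunraycer 2), and 19360 genes had enough counts to be tested.

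The MYB gene at the G locus, Prupe.5G196100.v2.1 (PpMYB25, a transcription factor needed for fruit hair), was measured first because it bears on the stated genotypes. Its expression was highest in TN11, at 44.7 ± 8.49 CPM (SD, n = 5), and lower in TN7, at 16.9 ± 2.00 CPM (SD, n = 4). Both nectarines had far lower levels, 3.28 ± 0.897 CPM in MN (SD, n = 5) and 2.43 ± 1.63 CPM in Sunraycer (SD, n = 5). MN, which shares the stated genotype Gg with TN7, had 5.13-fold less transcript than TN7 (log2 fold change −2.36, SE 0.333, adjusted p = 5.65e-05 in edgeR's quasi-likelihood test). Sunraycer had 18.2-fold less than TN11 (log2 −4.19, SE 0.349, adjusted p = 6.38e-08).

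Within the peaches the gene was 2.64-fold lower in Gg than in GG fruit (log2 −1.40, SE 0.328, adjusted p = 0.0112 in edgeR). Between MN and Sunraycer the log2 difference was 0.427 (SE 0.329, edgeR adjusted p = 0.265). The limma-voom estimate was 0.626, with a 95% interval of −0.137 to 1.39. The edgeR value of 0.427 moved with single libraries: leaving out each in turn gave 0.219 (without Sunraycer 10) to 0.869 (without Sunraycer 4, SE 0.283, edgeR adjusted p = 0.016). No library of a nectarine reached the level of any peach library. Exact two-sided permutation tests on CPM gave p = 0.0159 for MN against TN7, for Sunraycer against TN7 and for TN7 against TN11, and p = 0.00794 for MN and for Sunraycer against TN11. These are the smallest values that groups of these sizes can give, and over the 6 pairs they adjust to 0.0191. The exact permutation test between MN and Sunraycer gave p = 0.333.

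**Figure D1:**
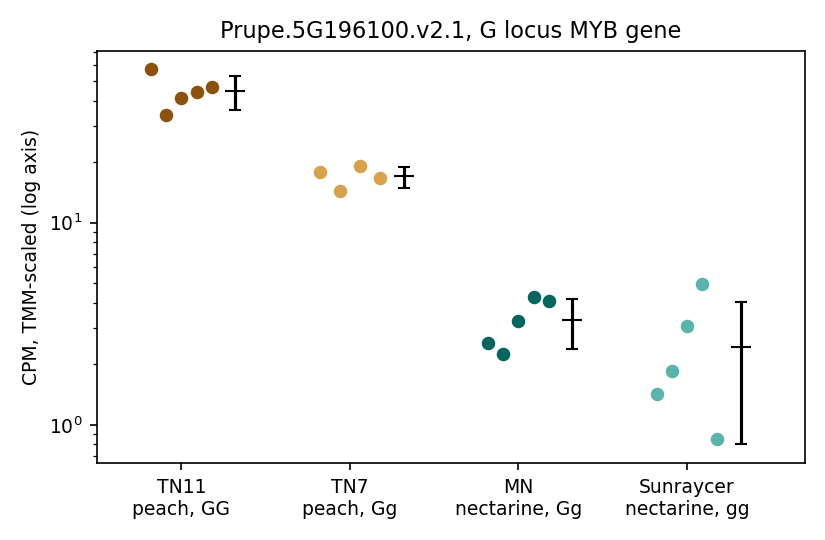
Expression of Prupe.5G196100.v2.1 in CPM on a log axis, with a point per library and the mean and SD beside each accession. TN11 averages 44.7, TN7 16.9, MN 3.28 and Sunraycer 2.43 CPM.

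The overall expression profiles separated the accessions and also showed a wide spread within them. The second principal component, with 26.1% of the variance, set both nectarines (18.3 to 77.8) apart from both peaches (−80.4 to −28.5). The first, with 44.5%, ran from MN (−110.1 to −27.0) to Sunraycer (59.5 to 172.3), and libraries of the same accession also spread along it. The peaches resembled each other most, with a mean correlation of log2 CPM of 0.944 between TN11 and TN7 libraries, and MN and Sunraycer least, with 0.862. Within accessions the correlations between libraries were 0.967 to 0.992 in TN11, 0.942 to 0.990 in TN7, 0.955 to 0.986 in MN and 0.907 to 0.979 in Sunraycer, across genes.

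**Figure D2:**
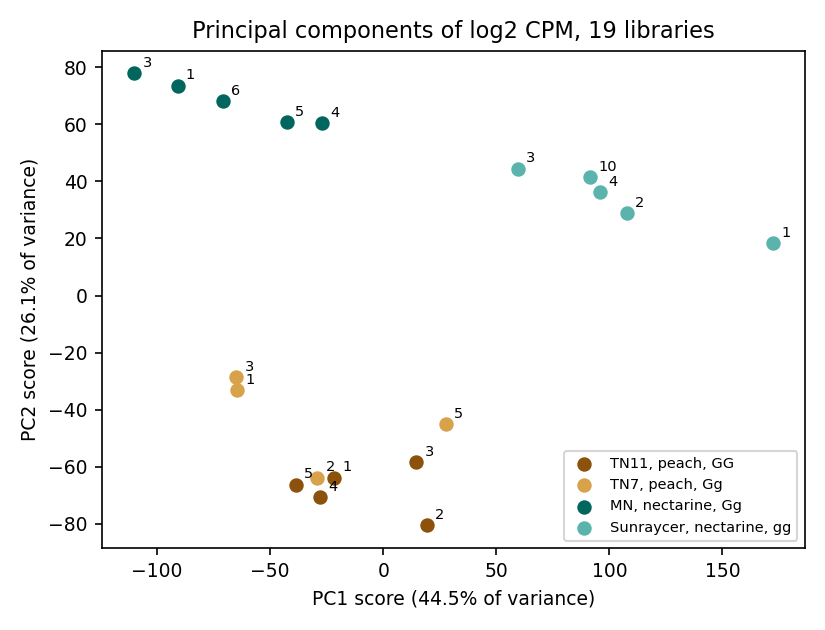
Scores of the 19 libraries on the first (44.5% of variance) and second (26.1%) principal components of log2 CPM, coloured by accession and numbered by replicate. Nectarines have positive and peaches negative scores on the second component, while MN and Sunraycer lie at opposite ends of the first.

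MN was compared with TN7 to ask what differs between a smooth and a hairy fruit with the same stated genotype. Most of the differing genes were lower in the mutant: 1470 fell and 529 rose, 1999 in all or 10.3% of the tested genes. The median size was 4.03-fold among the lower and 3.12-fold among the higher genes, and 429 lower and 103 higher genes differed by over 8-fold. Prupe.3G210300.v2.1 had 94.0 ± 16.9 CPM in TN7 (SD, n = 4) and no count in any MN library, at least 3390-fold lower (edgeR adjusted p = 9.44e-10). Prupe.1G328800.v2.1 had 233 ± 82.0 CPM in TN7 (SD, n = 4) and a single count over the MN libraries, in MN 5, a ratio of 25000 (counting interval 4480 to 986000). In the other direction, Prupe.8G245400.v2.1 reached 35.4 ± 5.73 CPM (SD, n = 5) and Prupe.4G260900.v2.1 16.9 ± 2.22 CPM (SD, n = 5) in MN. Neither had a count in TN7, so they were at least 1000-fold and at least 482-fold higher in MN. Adding the axis score as a covariate gave 1525 genes for MN minus TN7, 469 higher and 1056 lower. Of the 1999 genes, 1303 stayed called in that fit.

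Sunraycer was compared with TN11 as the homozygous ends of the G genotype, gg against GG. Here 1907 genes were higher and 1643 lower in the nectarine, 3550 in all or 18.3% of the tested genes. Prupe.3G210300.v2.1 was again absent from the nectarine and had 96.4 ± 12.5 CPM in TN11 (SD, n = 5), a difference of at least 2810-fold. Prupe.1G007400.v2.1 had 43.9 ± 6.88 CPM in TN11 (SD, n = 5) and no count in Sunraycer, at least 1290-fold lower. Prupe.2G107700.v2.1 had 102 ± 31.8 CPM in Sunraycer (SD, n = 5) against 2 counts over the TN11 libraries, a ratio of 5600 (counting interval 1550 to 46300). Prupe.4G284300.v2.1 had 19.3 ± 6.35 CPM in Sunraycer (SD, n = 5) and no count in TN11, at least 712-fold higher. Libraries of Sunraycer and TN11 also differed along the direction of spread within accessions, with axis scores of 0.535 ± 0.243 (SD, n = 5) and −0.0127 ± 0.183 (SD, n = 5), and with that score as a covariate 2016 genes were called, 685 higher and 1331 lower.

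The remaining nectarine and peach pairs gave 2904 genes for MN minus TN11 (752 higher, 2152 lower) and 3129 for Sunraycer minus TN7 (1880 higher, 1249 lower). With the axis score as a covariate, MN minus TN11 gave 2358 (674 higher, 1684 lower) and Sunraycer minus TN7 gave 1840 (774 higher, 1066 lower). Higher genes made up 25.9% of the calls of MN against TN11 and 26.5% against TN7. For Sunraycer the share was 53.7% against TN11 and 60.1% against TN7, but its direction depended on the fit. It was 34% and 42.1% with the axis score as a covariate, and against TN11 it was also 49.2% with limma-voom and 44.7% with glmTreat.

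**Figure D3:**
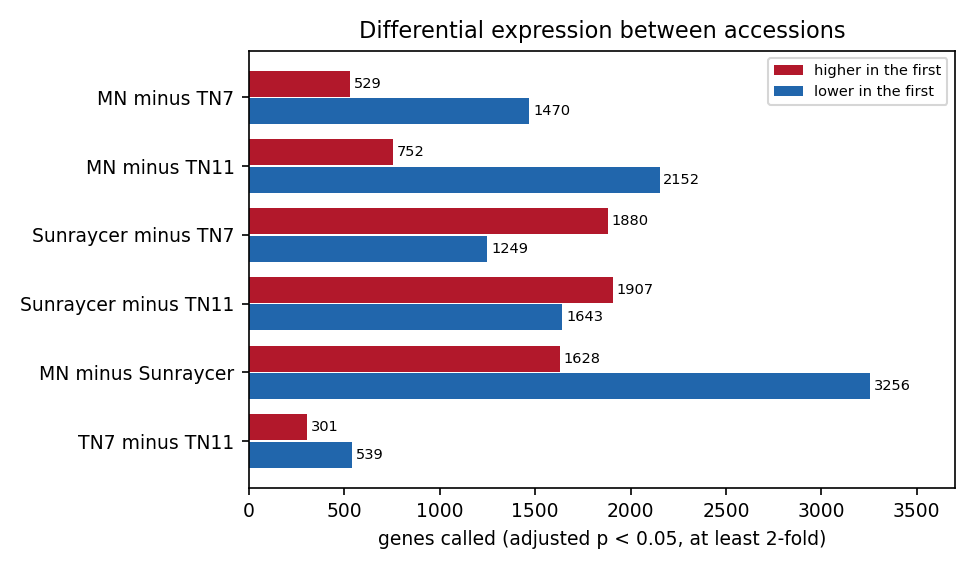
Genes called higher (red) and lower (blue) in the first accession of each of the 6 comparisons; bars are gene counts from 0. MN against TN7 gives 529 higher and 1470 lower genes, and TN7 against TN11 gives 301 and 539.

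Genes that separated both nectarines from both peaches were mostly genes with lower expression in nectarines. Of 600 such genes, 518 were lower and 82 higher in MN and in Sunraycer than in TN7 and in TN11. The other pairings of the accessions gave 195 genes (MN and TN7 against Sunraycer and TN11) and 60 genes (MN and TN11 against Sunraycer and TN7). The G locus gene was among the 518 and ranked 246 by its smallest log2 difference over the 4 comparisons. The median of that smallest difference was 4.88-fold among the lower and 3.85-fold among the higher genes. Prupe.3G210300.v2.1 led the lower genes, followed by Prupe.2G245800.v2.1, with 31.2 ± 10.2 CPM in TN11 (SD, n = 5), 22.5 ± 11 CPM in TN7 (SD, n = 4) and no count in either nectarine, at least 647-fold lower in each comparison.

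Prupe.8G245400.v2.1 led the genes higher in both nectarines, with 35.4 ± 5.73 CPM in MN (SD, n = 5), 2.09 ± 1.08 CPM in Sunraycer (SD, n = 5) and no count in either peach. Prupe.8G074400.v2.1 came next, with 17.4 ± 1.52 CPM in MN (SD, n = 5) and 7.38 ± 4.46 CPM in Sunraycer (SD, n = 5), against 3 counts over the TN11 and 1 over the TN7 libraries. MN minus TN7 and Sunraycer minus TN11 have no library in common, so their overlap is free of shared controls. They had 627 lower genes in common, where independent lists would share 125, and 147 higher genes, where independent lists would share 52.1. Genes called in opposite directions numbered 65 against 44.9 and 173 against 145. Across all tested genes, which are not independent replicates, the log2 fold changes correlated with r = 0.277 and rho = −0.10. MN minus TN11 and Sunraycer minus TN7, which also have no library in common, shared 618 lower genes (139 if independent) and 123 higher genes (73). There 492 genes were lower in MN and higher in Sunraycer, where independent lists would give 209, and 73 the reverse, where they would give 48.5; the correlation across genes was r = 0.127 and rho = −0.17.

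**Figure D4:**
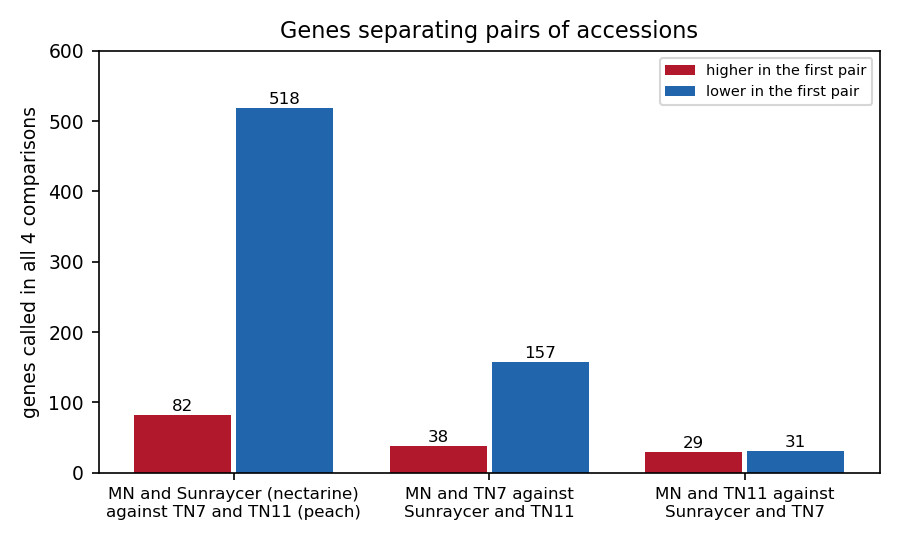
Genes called in the same direction in all 4 comparisons between pairs of accessions, for each way of pairing them. Nectarines against peaches give 82 higher and 518 lower genes, and the other pairings give 195 and 60 genes in all.

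Among the 600 genes shared by the nectarines, 44 were also called between the peaches, a larger share than the 4.34% called among all tested genes. Of the 518 lower genes, 21 were also called lower in TN7 (Gg) than in TN11 (GG), 7 were higher and 490 were not called. The 21 include the G locus gene and Prupe.1G007400.v2.1, which had 43.9 ± 6.88 CPM in TN11 (SD, n = 5), 6.57 ± 0.635 CPM in TN7 (SD, n = 4) and no count in a nectarine. Of the 82 higher genes, 12 were higher and 4 lower in TN7, and 66 were not called. No p-value is given for these directions, because the 600 genes were chosen with the same TN7 and TN11 libraries, and among all 840 genes called between the peaches 539 were lower in TN7.

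Between the peaches, stated Gg and GG, 840 genes were called, the fewest of the 6 pairs without a covariate: 301 were higher and 539 lower in TN7. With the axis score as a covariate the count was 1117. That fit gave fewer genes between the nectarines, but their axis scores did not overlap, so the counts do not rank the pairs fairly. Prupe.2G107700.v2.1 had 258 ± 53.7 CPM in TN7 (SD, n = 4) against 2 counts over the TN11 libraries, a ratio of 14100 (counting interval 3910 to 117000), and MN had 252 ± 34.9 CPM (SD, n = 5). Prupe.3G055500.v2.1 had 28.7 ± 4.50 CPM in TN7 (SD, n = 4) and no count in the other accessions, at least 1050-fold higher than in TN11. Prupe.1G205600.v2.1 and Prupe.6G139800.v2.1 had no count in TN7 and 110 ± 82.3 and 21.6 ± 9.76 CPM in TN11 (SD, n = 5), at least 3060-fold and 625-fold lower. The former varied widely between TN11 libraries, from 13.7 to 202 CPM.

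Between the nectarines MN (Gg) and Sunraycer (gg), 4884 genes were called, 25.2% of those tested, with 1628 higher and 3256 lower in MN. This was the highest count of the 6 pairs, but with the axis score as a covariate it was the lowest, at 427 (202 higher, 225 lower). Axis scores of MN (−0.662 to −0.173) and Sunraycer (0.275 to 0.936) did not overlap. That fit therefore cannot separate the axis from the difference between the accessions, and its low count is not evidence that they differ little. With adjusted p alone and no fold minimum, 5800 genes were higher and 5939 lower. Prupe.8G028000.v2.1 had 8.33 ± 0.626 CPM in MN (SD, n = 5) and no count in any other accession, at least 241-fold higher than in Sunraycer. Prupe.8G026800.v2.1 had 26.5 ± 2.31 CPM in MN (SD, n = 5) and 0.104 ± 0.232 CPM in Sunraycer (SD, n = 5), where its 8 counts all came from Sunraycer 1 (log2 8.05, SE 0.636, edgeR adjusted p = 1.01e-07; log2 12.1 without that library, a fitted value that depends on the prior count). Prupe.2G076700.v2.1 and Prupe.4G097000.v2.1 had no count in MN and 38.1 ± 21.7 and 14.7 ± 13.5 CPM in Sunraycer (SD, n = 5), at least 1350-fold and 528-fold lower in MN. The pair also lay farthest apart along the direction of spread within accessions, with axis scores of −0.421 ± 0.207 in MN (SD, n = 5) and 0.535 ± 0.243 in Sunraycer (SD, n = 5; exact permutation p = 0.00794, two-sided, adjusted 0.0238 over the 6 pairs). With that score as a covariate Prupe.4G097000.v2.1 was no longer called.

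MN differed in the same direction from each of the other accessions in 795 genes, 616 lower and 179 higher. The same count was 1427 for Sunraycer (1128 higher, 299 lower), 312 for TN11 and 117 for TN7. Prupe.8G028000.v2.1 and Prupe.1G273800.v2.1 led the genes higher in MN, the latter with 12.9 ± 0.740 CPM (SD, n = 5), 4 counts over the Sunraycer libraries and none in the peaches. Prupe.4G092800.v2.1 and Prupe.2G059400.v2.1 had no count in MN and mean levels of 5.38 to 9.76 CPM in the other accessions, at least 199-fold and 194-fold lower in MN. With the axis score as a covariate, 132 genes were called for MN alone (54 higher, 78 lower) and 150 for Sunraycer alone (87 higher, 63 lower). With the replicate number as a block, the count for MN alone was 527 (140 higher, 387 lower).

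The difference between nectarine and peach was itself compared between the pairs MN with TN7 and Sunraycer with TN11. It differed in 4199 genes, 1602 with a higher and 2597 with a lower value for MN minus TN7. The G locus gene was among them: its difference was smaller for MN minus TN7 by 1.83 on the log2 scale (SE 0.462, edgeR adjusted p = 0.00738). The larger part came from the lower level in TN7 than in TN11 (log2 −1.40), since MN minus Sunraycer was 0.427 (edgeR adjusted p = 0.265). With the axis score as a covariate, 493 genes were called (241 higher, 252 lower) and the value for the G locus gene was 1.46 (SE 0.646, adjusted p = 0.313). Without Sunraycer 1 and TN7 5, the libraries farthest from the rest of their accession, 2561 genes were called.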

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

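The tests of fruit stage, of an exchange with Sunraycer and of a variant allele were chosen after the results they concern had been seen, as was the fit with the axis score.

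The nectarine minus peach difference was not the same in MN with TN7 as in Sunraycer with TN11 for 4199 genes in edgeR. MN and Sunraycer lay at opposite ends of an axis along which libraries of every accession also spread, and gene slopes along it correlated between accessions by 0.395 to 0.708. Thinning all libraries to the smallest total kept 0.978 of the difference in axis score, which argues against depth. The difference was 0.957 without the 100 genes with most counts and 0.956 with them. The score is taken over all tested genes after TMM scaling, so leaving out 100 could hardly change it and decides little about abundant genes. Slopes estimated within the peaches correlated by −0.632 across genes with MN minus Sunraycer, which shares no library with them, while slopes within the nectarines correlated by −0.0197 with TN7 minus TN11. A difference in fruit stage or condition at collection is therefore a candidate explanation for part of the genes called between the nectarines, but it cannot be told apart from an inherited difference between accessions along the same genes.

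The G locus gene differed between the pairs by 1.83 on the log2 scale (adjusted p = 0.00738; 1.46, SE 0.646, adjusted p = 0.313 with the axis score as a covariate, which ends this call), and it was low in both MN, stated Gg, and Sunraycer, stated gg. The larger part of the 1.83 lay between the peaches, where TN7 minus TN11 was −1.40, while MN minus Sunraycer was 0.427. MN libraries taken from Sunraycer would leave few differences between them, and 4884 genes were called. In the fit with the axis score as a covariate, MN minus TN7 for this gene was −2.49, so position on the axis is not the whole cause. Without the covariate, the 20 tested genes on each side had a median MN minus TN7 value of 0.0583 (quartiles −0.581 and 0.322). This median argues against loss of a wide region in MN. Reads of a variant allele that fail to align could lower the level in either nectarine: Sunraycer still had 2.43 CPM, but how many reads were lost cannot be known without the sequence. A change at or near the gene in MN, or in a regulator of it, stays open as an untested hypothesis.

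The other genes whose nectarine minus peach difference differed between the pairs are given as MN minus TN7 less Sunraycer minus TN11, on the log2 scale and with edgeR adjusted p; fitted values for genes with no or few counts in a group depend on the prior count. Prupe.1G328800.v2.1 had −2.66 (0.0352), which rests on 1 count in MN 5 against 7 counts over the Sunraycer libraries; without MN 5 its MN minus TN7 value went from −13.9 to −15.2. Prupe.2G107700.v2.1 had −12.1 (1.02e-11) and Prupe.4G284300.v2.1 −9.06 (0.000603). Prupe.2G076700.v2.1 had −11.1 (1.56e-06), Prupe.4G092800.v2.1 −11.0 (2.49e-06) and Prupe.2G059400.v2.1 −9.89 (3.88e-10). Prupe.8G026800.v2.1 had 7.18 (1.12e-05) and Prupe.6G139800.v2.1 12 (3.1e-06).

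Single libraries lay far from the others of their accession in 8 of 55 sets of values examined, where chance would give about 2.75 for independent, normally distributed values. Most sets were CPM of genes picked for large differences, some near 0, and they reuse the same libraries. All 8 values lay above the others, as skewed values would, so the excess does not show that the libraries were unusual. Prupe.1G205600.v2.1 was 2430 CPM in Sunraycer 4 against 579 to 1110 in the others, and 21 CPM in MN 5 against 0 to 2.75. Prupe.4G097000.v2.1 was 15.4 CPM in TN11 2 against 0.128 to 1.66, and 1.72 CPM in TN7 5 against 0 to 0.0933. Prupe.2G076700.v2.1 was 75.6 CPM in Sunraycer 1 against 20 to 35. Prupe.2G245800.v2.1 was 38.8 CPM in TN7 2 against 15.7 to 19.1. Prupe.6G139800.v2.1 was 4.29 CPM in Sunraycer 3 against 2.67 to 3.04. Prupe.4G284300.v2.1 was 0.718 CPM in MN 3 against 0.226 to 0.356.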

How the results depend on the processing

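The fits without Sunraycer 1 and TN7 5 and with the axis score were chosen after the data were seen. Of 412 counts of genes under an alternative, 374 stayed within 1.5 times the value reported. Of 189 values of the G locus gene, 188 were called or not called as before, on p and fold taken jointly. The same held for 646 of 647 values of the other named genes, and none reversed. The exceptions, both with the axis score as a covariate, were the interaction of the G locus gene (1.46, adjusted p = 0.313, from 1.83) and Prupe.4G097000.v2.1 in MN minus Sunraycer (−4.94). Leaving out each library moved no count by over 1.5 times: the shared nectarine genes ranged from 520 to 615, MN minus TN7 from 1582 to 2316, MN minus Sunraycer from 3854 to 5577 and the interaction from 2971 to 4919. The G locus gene ranged from −2.47 to −2.25 in MN minus TN7 and from 0.219 to 0.869 in MN minus Sunraycer, where leaving out Sunraycer 4 took the adjusted p to 0.016. The shared genes numbered 592 with DESeq2 size factors, 624 without a filter, 524 with the stricter one, 645 with DESeq2 and 607 with limma-voom, and 587, 577, 522, 590 and 580 of the 600 were kept.

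The thresholds changed every count, by construction. Adjusted p alone gave 3960 genes for MN minus TN7, 8332 for Sunraycer minus TN11, 6473 for MN minus TN11, 6967 for Sunraycer minus TN7, 11739 for MN minus Sunraycer, 1523 for TN7 minus TN11 and 7219 for the interaction, with 973 shared nectarine genes, 353 and 122 for the other pairings, and 1845, 3782, 212 and 636 for MN, Sunraycer, TN7 and TN11 alone. A test against 2-fold (glmTreat) gave 831, 1359, 1315, 1286, 2056, 300, 946, 330, 43, 18, 224, 372, 51 and 99 in the same order.

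With the axis score as a covariate, the counts were 427 for MN minus Sunraycer, 493 for the interaction, 2016 for Sunraycer minus TN11, 1840 for Sunraycer minus TN7, 59 and 20 for the other pairings, and 132 and 150 for MN and Sunraycer alone. For the genes called in MN minus Sunraycer the median size went from 1.68 to 0.584 on the log2 scale while the median SE went from 0.378 to 0.550, and 63.1% of these genes kept their sign. Axis scores of MN and Sunraycer did not overlap, so this fit can also take away part of the difference between the accessions. The shared nectarine genes numbered 571, and 497 of the 600 were kept. Without Sunraycer 1 and TN7 5 the interaction gave 2561 genes, and the cause was not tested; the shared nectarine genes numbered 632.

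Over all accessions the replicate numbers do not pair the samples: same-numbered libraries correlated in their deviations by −0.607 to 0.536, with 8 of 21 pairs over 0.1, and 5 of 17 libraries correlated best with their own number. With the replicate block, 527 genes were called for MN alone, and the other counts stayed within 1.5 times, the shared nectarine genes at 529 and MN minus TN7 at 1520. The share of higher genes in Sunraycer minus TN11 was 47.5% with the block. The gene lists with camera and fry were not run, since no product descriptions matched the identifiers, and neither was leaving out replicate 4 of TN7, which was not analysed here. Depth limits what is said of genes without counts. Changes of 2-fold were missed in most genes simulated with them, in part because a call requires an estimate of at least 2-fold.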

Other observations

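The tests of chromosome placement, of neighbours, of differences between accessions and of silent genes were chosen after the results had been seen.

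Silent genes set the nectarines apart from the peaches. At most 3 counts over all MN libraries and at most 3 over all Sunraycer libraries, with a mean of at least 1 CPM in both TN7 and TN11, were found for 23 genes. The reverse, silent in both peaches, held for 3 genes, and the other pairs of accessions gave 2 (MN and TN7), 1 (MN and TN11), 1 (Sunraycer and TN7) and 3 (Sunraycer and TN11). Single accessions were silent for 9 genes in MN, 6 in Sunraycer, 4 in TN11 and 4 in TN7. Reads of strongly diverged alleles and absent genes would look alike here, and neither was tested.

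Genes lower in both nectarines often stood next to each other in the order of the identifiers. Among the 518 there were 45 adjacent pairs of tested genes, where 1000 random sets of the same size had a mean of 13.8 and a highest value of 26, so chance placement alone does not account for it. The 82 higher genes had 12 adjacent pairs against a highest random value of 3. Sets of a single accession did the same, with 75 pairs among the 616 genes lower in MN alone (highest random value 36), so adjacency is not particular to the nectarine genes. Tandem copies that vary together, or inherited segments, may underlie the 45 pairs, and these were not told apart.

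The 179 genes higher in MN alone seemed to gather on chromosomes 2 and 8, which held 90 where 39.5 would be proportional. Shifting the calls along the gene order gave some pair of chromosomes as enriched in a share of 0.167 of 2000 shifts. For chromosomes 2 and 8 themselves, picked after the counts were seen, 244 of 10000 shifts held as many genes. Shifts keep neighbouring calls together and can carry them as a block onto other chromosomes. The share of 0.167 thus gives no support for a gathering beyond chance, but it does not show that the 90 genes lie there by chance.

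More genes separated nectarines from peaches (600) than separated the other pairings (195 and 60). With the axis score as a covariate 571 genes were found and at most 59 for another pairing. This fit cannot decide the role of the axis. Mean axis scores of TN11 (−0.0127) and TN7 (−0.0705) lay between those of MN (−0.421) and Sunraycer (0.535). A linear effect of the axis would shift the nectarines in opposite directions from the peaches, so the covariate could not remove this set. The other pairings also require a call between MN and Sunraycer, which the covariate cut to 427 genes. Differences between accessions unrelated to the fruit surface could give the same order, because 1 of 3 pairings has to be the highest, and 3 pairings are too few to exclude chance. Shared ancestry of the accessions was not analysed here.

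When libraries were shuffled between accessions, only 1 of 30 splits, the real one, gave as many genes in each case. Mixing accessions widens the spread within each group, so few or no calls could come from other splits. The splits thus show that accessions differ, but not whether genotype or fruit surface is the reason. For pairs of accessions, 30 of 126 possible splits were used, and the hint of pairing between MN and TN7 was ignored. In fits on the groups compared alone, the real and the highest other values were 1883 and 0 for MN minus TN7, 3200 and 0 for Sunraycer minus TN11, 2795 and 0 for MN minus TN11, 4290 and 0 for MN minus Sunraycer and 867 and 0 for TN7 minus TN11. Sunraycer minus TN7 gave 2337 against 1095, the latter from a split that moved Sunraycer 3 alone to the side of TN7. In fits of all accessions the values were 600 and 0 for the shared nectarine genes, 795 and 0 for MN alone and 4199 and 0 for the interaction.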
